A study of Mus musculus with 11 samples.

How the data were processed

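Gene expression was measured in mouse embryonic fibroblasts (MEFs) that carried a doxycycline-responsive transactivator and a Nanog-GFP reporter. The cells were transfected with piggyBac transposons, DNA elements that a transposase inserts into the genome, which expressed a transgene together with the red fluorescent protein mCherry once doxycycline was added. Per the labels, 8 transposons carried a polycistronic reprogramming cassette (EB-C5, MKOS, OK+9MS, OKMS, OKN-HAMS, OSKM, STEMCCA and WTSI), 2 carried Klf4 alone (Klf4S and Klf4L) and 1 carried lacZ. Cells of the 10 reprogramming constructs were sorted for mCherry on day 6. The lacZ cells were harvested on day 2 without that sort, so day and sort cannot be told apart from the transgene in any comparison with lacZ.

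Each construct was measured on 1 Affymetrix mouse gene array. The deposited values are log2 expression values that the authors made with RMA (background correction, normalization between arrays and probe set summarization), per the submitters' processing notes; the RMA version is not given in the sources used here. The values spanned nearly the same range on all 11 arrays, with medians from 7.188 to 7.269, and were analysed as deposited. Large differences can be understated in RMA values. Signals under 6 cannot be told from background by these values alone, so a difference from such a level is a lower bound in size, and its SE does not cover that limit.

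The table held 28856 probe sets. A probe table paired 21789 of them with 1 gene symbol, 1621 with several symbols and 5446 with none, and 21698 of the 1-symbol probe sets matched a current Entrez entry without a change of symbol. Probe sets with several or no symbols were left out of the gene analysis. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which gave 19938 genes. No filter on dim genes was applied. The part of each transcript that the probes cover is not given in the sources used here, so signal from a transgene and from the cell's own copy could not be separated.

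The 8 cassettes formed 1 group, the 2 Klf4 constructs another, and the lacZ array stood by itself. The spread within a group was the spread between different constructs, each measured once; p-values measure that spread and not the spread between repeated cultures. Differences between the 3 groups were fitted in a single model over all 11 arrays with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment over all genes, with calls at an adjusted p under 0.05 and 8 residual degrees of freedom. The lacZ array added no spread of its own and was assumed to vary like the other groups. The effect of the 9-residue extension of Klf4 was fitted over the 4 arrays whose labels name it or its partner (OKMS, OK+9MS, Klf4S and Klf4L) with context as a second term, which left 1 residual degree of freedom. Comparisons of single arrays were described by counts of genes at 2-fold or more (1 on the log2 scale), with no p-value. The labels used here do not say which Klf4 form the other 6 cassettes carry, and they were not grouped by it.

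Before the data were examined, 23 gene lists with 473 entries were fixed, of which 438 entries were measured. Lists were compared between groups with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Between single arrays, a list's median difference was placed among those of 10000 random lists of the same size drawn from 20 bins of mean expression. Genes were named by a rule fixed at the same time: the 10 called genes with the largest difference in each direction per comparison, up to 4 called members per list, the 4 reprogramming factors, the 8 genes with the largest difference in the same direction in both contexts of the extension and the 5 largest in each context, and the 3 largest differences of each cassette from the median of the other 7. Predicted genes, clone names, small RNAs and olfactory and vomeronasal receptors were counted and not named, and genes of embryonic stem cells near the array's low end were named only with their level.

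Each procedure was tested on simulated data for the 19938 genes. With 200 genes changed, the fit recovered 61.5% of changes of 1 on the log2 scale and 86% of changes of 2 for the cassettes against lacZ. The shares were 56% and 86% for Klf4 alone against lacZ and 74% and 96% for the cassettes against Klf4 alone. Each of these fits also gave 7 to 12 false calls. Noise on every array, lacZ included, was drawn from the fitted shared spread of each gene. These shares therefore cannot check whether lacZ varies like the other groups. The fit of the extension recovered 0% at both sizes. In the list test 1 of 1 raised lists was called and 0 of 22 others, and among the random-list percentiles the 1 raised list and 1 of 45 other results lay outside the central 95%. The simulated noise was independent between genes. These checks therefore do not show how often lists whose members move together are called or lie outside that range.

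Alternatives were quantile normalization, centring on the array median, a filter on genes below the median level, the mean of a gene's probe sets, fits on the compared groups alone, an intensity trend with a robust prior, array weights, a minimum fold, a 1.5-fold threshold and leaving out each construct. Overlap between comparisons that share the lacZ array was set against 100 simulations of unchanged constructs. The software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.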

Results

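The data were 11 arrays of MEFs, 1 for each transgene: 8 polycistronic reprogramming cassettes, 2 forms of Klf4 alone and lacZ. A polycistronic cassette encodes several reprogramming factors, here from the set of Oct4 (Pou5f1), Sox2, Klf4 and c-Myc, in a single transcript. The series asked how construct design, and the amount and form of Klf4 in particular, affects gene expression early in reprogramming, with lacZ as the reference for all constructs. The number of arrays limits the precision, since no construct was measured more than once.

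The signals of the 4 factors were read first on every array. The Pou5f1 signal lay between 11.89 (STEMCCA) and 13.22 (OKMS) in the 8 cassettes, against 6.06 in Klf4S, 5.85 in Klf4L and 6.09 in lacZ. The Klf4 signal lay between 9.47 in lacZ and 10.20 in WTSI, so it hardly separated the constructs that carry Klf4 from lacZ. Myc, the proliferation-promoting transcription factor, read from 9.86 (EB-C5) to 10.91 (OK+9MS) in the cassettes, 9.05 in Klf4S, 8.65 in Klf4L and 9.54 in lacZ. Sox2 read between 6.22 and 6.88 in 7 cassettes and 7.76 in WTSI, against 6.79 in lacZ. The readings in the 7 cassettes and lacZ lay below the array medians, which ran from 7.188 to 7.269. Which part of each transcript the probes cover is not given in the sources used here, so a flat signal does not show that a factor was not expressed from its transgene.

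The cassettes were compared with lacZ to find what reprogramming factors together changed in fibroblasts. Pou5f1 is itself a factor of the cassettes, so its signal can be that of the transgene and does not show a response of the cells. Pou5f1, the core pluripotency transcription factor, rose most (log2 difference 6.67 ± 0.41 SE, n = 8 against n = 1, limma adjusted p = 0.000184). The cell adhesion molecule Ceacam1 rose by 5.43 ± 0.57, the palmitoyltransferase Zdhhc23 by 5.32 ± 0.60, the secreted apelin receptor ligand Apela by 5.12 ± 0.68 and the neurofilament subunit Nefl by 4.95 ± 0.99. Shisa3 (4.19), the sialomucin Podxl (3.88), the actin-binding protein Avil (3.75), the nuclear pore protein Nup210 (3.62) and the retinaldehyde dehydrogenase Aldh1a1 (3.47) rose as well. The steroid dehydrogenase Hsd3b6 fell most (-3.53 ± 0.12, limma adjusted p = 1.5e-06), followed by Gpr149 (-2.95), the Ras exchange factor Rasgrp3 (-2.90), the ankyrin-repeat protein Ankrd1 (-2.81), the smooth muscle potassium channel subunit Kcnmb1 (-2.79), the transcription factor Gata3 (-2.64), Coch (-2.64), the glycosyltransferase B3gnt5 (-2.58), the lipase Lipg (-2.56) and Rab3b (-2.51). The lower level read 5.42 for Ceacam1 and 5.67 for Zdhhc23 (both in lacZ) and 5.66 for Hsd3b6 (in the cassettes), too low to be told from background, so these 3 differences are lower bounds in size. In all, 409 of 19938 genes changed, 91 higher and 318 lower, so that 22.25% were higher, against 41.4% of the 186 called among genes above the median level. The count was 272 without OSKM, 241 without OK+9MS, 734 without STEMCCA, and 184 without either Klf4 construct in turn or with the arrays of the compared groups alone. The lacZ cells were harvested on day 2 and unsorted, and the cassette cells on day 6 after sorting.

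Among the fixed lists, 7 of 23 stood apart from other genes in this comparison by camera at the preset correlation, and none did with an estimated correlation. The 7 include the list of reprogramming factors, which the cassettes supply, so that call can follow from the transgenes alone. The epithelial list had a median difference of 1.37 over 30 genes (camera adjusted p = 1.6e-06, adjusted p = 0.7962 with an estimated correlation), yet 0 members passed the test singly, over all genes or adjusted over the list alone. The cassettes themselves were far apart in these genes, with list means from 7.34 in WTSI to 9.68 in OKN-HAMS against 7.17 in lacZ. The list of MYC targets and ribosome biogenesis, genes that serve growth, had a median of 0.53 with 0 of 26 members past the test, over all genes or adjusted over the list alone (camera adjusted p = 1.66e-09, adjusted p = 0.6788 with an estimated correlation). Interferon-response genes, which encode antiviral proteins, lay lower in the cassettes, with a median of -1.16 over 23 genes (camera adjusted p = 3.945e-08, adjusted p = 0.6788 with an estimated correlation). Of these, 2 fell over all genes, Oasl1 (-2.16 ± 0.19) and Cmpk2 (-2.08 ± 0.26), and 6 adjusted over the list alone. The list of the 4 reprogramming factors had a median of 0.76, with Pou5f1 called over all genes and 2 members adjusted over the list alone (camera adjusted p = 0.0003376, adjusted p = 0.5105 with an estimated correlation). The smooth muscle and TGF-beta list had a median of -0.85 with 0 of 17 members called (camera adjusted p = 0.0001478, adjusted p = 0.7962 with an estimated correlation).

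Early pluripotency genes had a median difference from lacZ of 0.73 over 15 genes (camera adjusted p = 0.0003376, adjusted p = 0.5105 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. In the late pluripotency list, whose 22 genes had a median of 0.21 (camera adjusted p = 0.0507), L1td1, an RNA-binding protein of embryonic stem cells, rose by 2.45 ± 0.51 to a mean of 8.78, and the transcription factor Klf2 fell by 0.62. The keratinocyte list had a median of 0.71 with 0 of 29 called (camera adjusted p = 0.01206, adjusted p = 0.8627 with an estimated correlation). G2/M genes, which drive mitosis, had a median of -0.17 and replication genes of 0.07, with 0 members of either list called.

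The Klf4 constructs were compared with lacZ to see what Klf4 changed without the other factors. Crnn, which encodes cornulin of the cornified layer, rose by 3.02 ± 0.39 SE (n = 2 against n = 1, limma adjusted p = 0.01038). The serpins Serpinb11 and Serpinb7 rose to 7.79 and 7.47 from lacZ levels of 4.76 and 4.68, at the low end of the array, so their differences have only lower bounds. Cadm3 (2.98), the chemokine-binding receptor Ackr1 (2.60), the secreted carbonic anhydrase Car6 (2.60), the endothelin Edn2 (2.45), the laminin chain Lama4 (2.37), Gpm6b (2.31) and the interleukin-1 family cytokine Il1f9 (at least 2.29, from 5.42 in lacZ) rose too. Among the 10 largest decreases were Prr11 (-2.73), the histone chaperone Asf1b (-2.71), the kinase Melk (-2.31), Depdc1a (-2.29), the cytokinesis motor Kif23 (-2.25) and the spindle protein Nusap1 (-2.22). Hsd3b6 (-3.37, a lower bound in size, since it read 5.82 in Klf4 alone), Rasgrp3 (-2.58), Kcnmb1 (-2.49) and Ankrd1 (-2.41) fell here as in the cassettes. In all, 149 genes changed, 54 higher and 95 lower. The share higher was 36.2%, against 23.4% of the 77 called among genes above the median level and 55.6% of the 36 called without Klf4L.

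The G2/M list was lower in Klf4 alone than in lacZ as a set, with a median of -2.05 over 26 genes (camera adjusted p = 5.55e-34, adjusted p = 0.3801 with an estimated correlation). Of its members 9 fell over all genes, among them Prc1 (-2.14 ± 0.39) and Tpx2 (-2.12 ± 0.34), both of the mitotic spindle, and 26 fell adjusted over the list alone. Replication genes had a median of -1.43 over 24 genes (camera adjusted p = 2.7e-18, adjusted p = 0.6176 with an estimated correlation), with Gins2 called over all genes and 21 members adjusted over the list alone. The MYC and ribosome list had a median of -0.41, with 0 called over all genes and 1 adjusted over the list alone (camera adjusted p = 4.95e-06, adjusted p = 0.7785 with an estimated correlation). Keratinocyte genes had a median of 0.99 with 0 of 29 called (camera adjusted p = 0.001389, adjusted p = 0.8088 with an estimated correlation), and mesenchymal genes a median of 0.38 with 0 of 29 called over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0002481, adjusted p = 0.8088 with an estimated correlation). Oasl1 (-1.78) and Cmpk2 (-1.70) fell, in an interferon list whose median was -0.21 (camera adjusted p = 0.03697, adjusted p = 0.8745 with an estimated correlation). The p53 and senescence list had a median of 0.22 with 0 of 17 called over all genes or adjusted over the list alone (camera adjusted p = 0.03729, adjusted p = 0.7785 with an estimated correlation). The spread behind these calls came mostly from the cassettes: on the 3 arrays compared alone limma called 0 genes, and the count was 40 without Klf4S, 36 without Klf4L, 93 without OK+9MS and 268 without MKOS.

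Calls against lacZ shared 8 genes higher in both groups, of 91 and 54, and 56 lower in both, of 318 and 95. Independent lists of these sizes would share 0.247 and 1.52 genes. Simulated unchanged groups against the same lacZ array shared 0, a value that sets no level for lists of these sizes, since groups without effects are not made to give calls. With a single lacZ array the control could not be split, so how much of the overlap comes from that array is not known.

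The cassettes were compared with Klf4 alone on the same day and after the same sort. Beside the further factors, the amount and form of Klf4 may differ between these groups, and their parts in the differences cannot be told apart. Pou5f1 was higher by 6.81 ± 0.31 SE (n = 8 against n = 2, limma adjusted p = 5.7e-06), Zdhhc23 by 5.15 ± 0.45, Nefl by 5.11 ± 0.74, Shisa3 by 4.24 ± 0.34, Apela by 3.90 ± 0.50, Bex1 by 3.88 ± 0.39 and the adaptor subunit Ap1s3 by 3.86 ± 0.37. Avil (3.51), Them5 (3.42) and Hpdl (3.37) were also among the 10 most increased genes. The Klf4 alone levels of Pou5f1 (5.95), Zdhhc23 (5.84) and Bex1 (5.06) could not be told from background, so their differences are lower bounds. Lower in the cassettes were the keratin Krt90 by -4.37 ± 1.25, the cornified envelope protein Cnfn by -4.00 ± 0.71 and the uroplakin Upk1b by -3.80 ± 0.75. Serpinb11 and Serpinb7 were lower too, at 4.78 and 4.67 in the cassettes, the low end of the array, against 7.79 and 7.47 in Klf4 alone. Cadm3 (-3.12), the betaine transporter Slc6a12 (-2.86), Pamr1 (-2.85), the growth factor Pgf (-2.84) and the homeobox gene Isx (-2.80) were lower too. In all, 2885 genes differed, 1267 higher and 1618 lower, while 509 of the 811 that differed by at least 2-fold were higher and 302 lower. The count was far lower when either Klf4 construct was left out. Every fit used a shared spread for all groups, so the Klf4 arrays were assumed to vary like the cassettes in the full fit too. The difference between the 2 Klf4 arrays had an SD of only 0.126 over genes, and each array counted as a separate measurement.

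Cell division genes separated the cassettes from Klf4 alone. All 26 measured G2/M genes were higher in the cassettes, over all genes and adjusted over the list alone, with a median of 1.87 (camera adjusted p = 3.6e-27, adjusted p = 0.2594 with an estimated correlation). Examples were the mitotic kinases Bub1 (2.54 ± 0.39), Aurka (2.44 ± 0.30) and Plk1 (2.17 ± 0.27) and the spindle protein Nusap1 (2.30 ± 0.25). Of 24 replication genes 23 rose, over all genes and adjusted over the list alone, with a median of 1.52 (camera adjusted p = 3.5e-19, adjusted p = 0.263 with an estimated correlation), among them the helicase subunits Mcm5 (2.31 ± 0.40) and Mcm6 (2.31 ± 0.26), Mcm10 (2.75 ± 0.43) and the polymerase Pole (2.02 ± 0.38). Of 26 MYC and ribosome genes 22 rose over all genes and 26 adjusted over the list alone (median 1.00, camera adjusted p = 1.3e-19, adjusted p = 0.2594 with an estimated correlation). They included the transferrin receptor Tfrc (2.70 ± 0.26), the pseudouridine synthase Dkc1 (1.80 ± 0.31), the RNA polymerase I subunit Polr1b (1.52 ± 0.28) and Rrp9 (1.39 ± 0.40), and Myc itself, a factor of the cassettes, rose by 1.77 ± 0.24.

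Mesenchymal genes were lower in the cassettes than in Klf4 alone, with a median of -0.80 over 29 genes (camera adjusted p = 2.85e-07, adjusted p = 0.513 with an estimated correlation). Against lacZ the same list had a median of -0.20 in the cassettes, with 0 of 29 called over all genes or adjusted over the list alone (camera adjusted p = 0.4924), and of 0.38 in Klf4 alone. The collagens Col3a1 (-1.19 ± 0.34), Col1a2 (-0.99 ± 0.29), Col5a1 (-0.96 ± 0.25) and Col6a1 (-0.58 ± 0.17) fell, and 15 members fell adjusted over the list alone. Of 15 early pluripotency genes 5 rose over all genes and 6 adjusted over the list alone (median 0.77, camera adjusted p = 0.001519, adjusted p = 0.263 with an estimated correlation). The alkaline phosphatase Alpl was higher by 2.98 ± 0.58, the let-7 regulator Lin28b by 1.08 ± 0.29 from a level of 5.89 and the ubiquitin ligase Trim71 by 0.81 ± 0.23. Epcam, an epithelial adhesion molecule also counted in that list, was higher by 3.12 ± 0.89, from 6.00 in Klf4 alone. Of 30 epithelial genes 3 rose over all genes and 0 adjusted over the list alone, with Lsr (1.26 ± 0.34) and the transcription factor Elf3 (0.66 ± 0.19) beside Epcam (median 0.80, camera adjusted p = 0.0005627, adjusted p = 0.6012 with an estimated correlation). In the keratinocyte list the median was -0.14 and Sbsn, suprabasin of the epidermis, fell by 2.41 (camera adjusted p = 0.5415). L1td1 rose by 2.34 ± 0.38 and Lefty1 fell by 0.37 in the late pluripotency list, with a median of 0.21 (camera adjusted p = 0.01235, adjusted p = 0.513 with an estimated correlation). Interferon-response genes had a median of -0.77 with 0 of 23 called over all genes or adjusted over the list alone (camera adjusted p = 0.0005009, adjusted p = 0.513 with an estimated correlation). The smooth muscle and TGF-beta list had a median of -0.82, with Tgfb2 called lower over all genes and 3 of 17 members adjusted over the list alone (camera adjusted p = 0.002065, adjusted p = 0.513 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.17 with 0 of 24 called (camera adjusted p = 0.001907, adjusted p = 0.513 with an estimated correlation), and the 4 reprogramming factors a median of 1.11 with Pou5f1 and Myc called (camera adjusted p = 0.0008446, adjusted p = 0.2594 with an estimated correlation). In all, 12 of the 23 lists were called in this comparison at the preset correlation and 0 with an estimated one. The 12 include the reprogramming factors, which the cassettes supply.

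**Figure D1:**
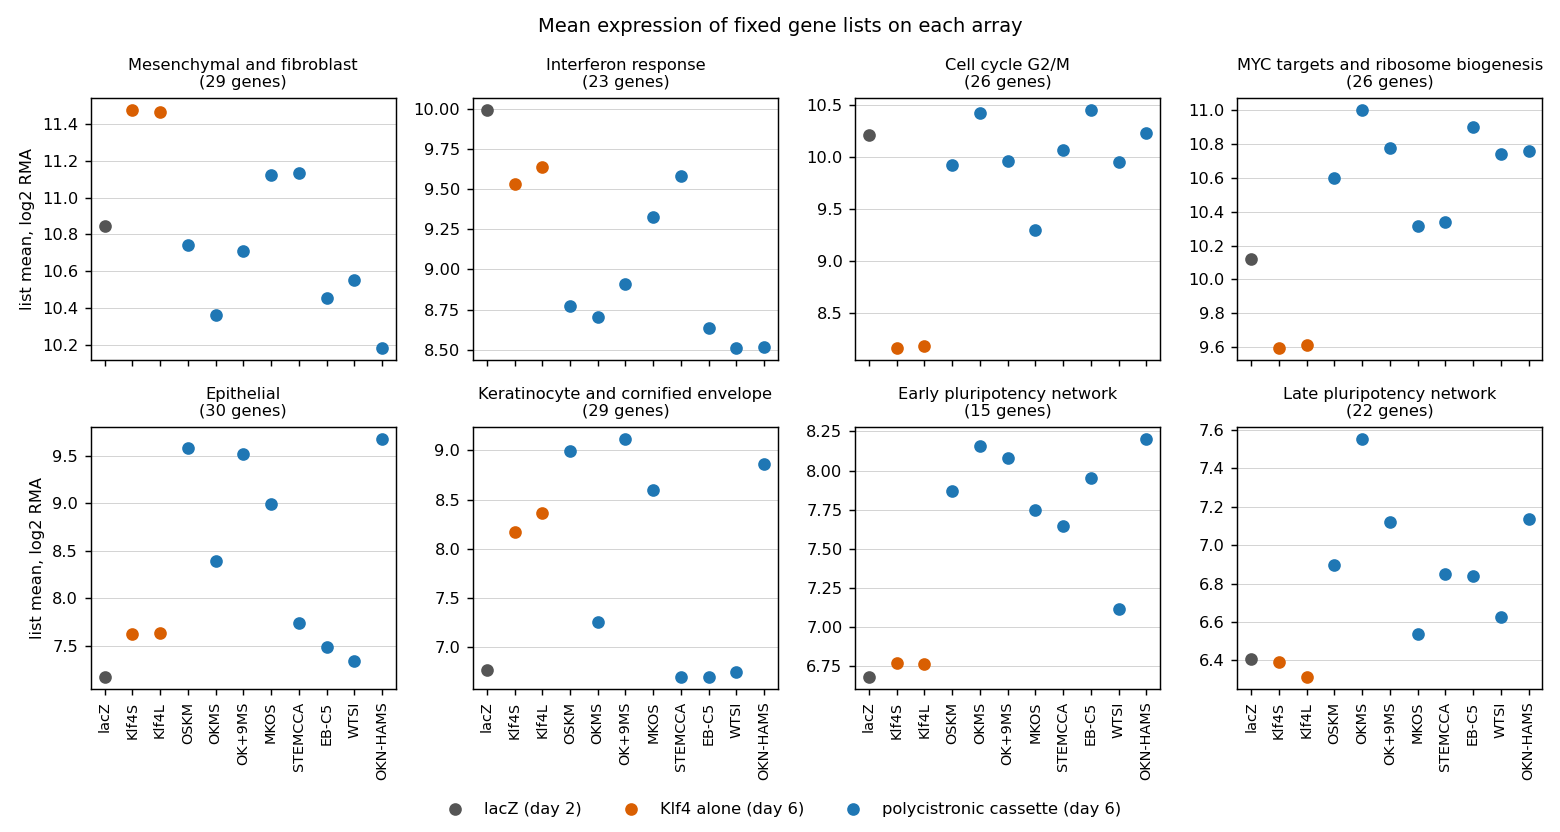
Mean log2 RMA expression (vertical axes) of 8 fixed gene lists on each of the 11 arrays (horizontal axes), with 1 point per array: lacZ grey, Klf4 alone orange, cassettes blue. The G2/M list read 8.16 in Klf4S and 8.18 in Klf4L and at least 9.30 in every other array, and the keratinocyte list ranged from 6.69 to 9.12 among the cassettes.

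The series also asked for changes common to all constructs. Of the 19938 genes, 82 were at least 2-fold higher and 102 at least 2-fold lower than lacZ in all 8 cassettes. Unchanged constructs set against a shared lacZ array gave 11.9 and 11.6 on average over 100 simulations, with at most 22 and 21. The simulations held no effect of day or sort, which would also give changes common to all 8 cassettes, so the excess is not assigned to the transgenes. Of the 82 genes, 25 were also 2-fold higher in both Klf4 constructs and 52 lay under 2-fold in both. Of the 102 genes, 60 were also lower in both Klf4 constructs and 35 under 2-fold in both. The number of genes at 2-fold or more differed between constructs, from 544 in STEMCCA and 873 in MKOS over 1069 in WTSI, 1203 in OK+9MS, 1338 in OSKM, 1497 in OKMS and 1514 in EB-C5 to 1819 in OKN-HAMS. Klf4S had 775 and Klf4L 791. These counts have no replicate check.

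The 9-residue extension of Klf4 was compared in 2 contexts, OK+9MS against OKMS and Klf4L against Klf4S, with a single array each and so no replicate check. In the cassette, keratinocyte genes were far higher with the extension: the keratins Krt16 (at least 5.31, from 5.95 in OKMS), Krt14 (4.98) and Krt6a (4.32), the epidermal lipoxygenase Alox12b (4.67) and the kallikrein Klk10 (4.44), together with the proteoglycan Srgn (5.06). The thyrotropin-releasing hormone gene Trh was lower (-4.29, from 11.11 in OKMS to 6.82), as were Pllp (-3.19), the stem cell nuclear receptor Nr0b1 (-2.97, from 11.81 to 8.83), Fndc3c1 (-2.82) and the adhesion molecule Cadm1 (-2.64). In all, 459 genes were at least 2-fold higher and 175 at least 2-fold lower. In Klf4 alone 0 genes reached 2-fold, and the largest difference was 0.93, for the collagenase Mmp13.

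Some epidermal genes were higher with the extension in both contexts. Sprr1b, a cornified envelope precursor, differed by 3.27 in the cassette and 0.76 in Klf4 alone, the skin protease Asprv1 by 2.42 and 0.68, and Krt6a by 4.32 and 0.58. Sprr2b differed by 1.69 and 0.61, from levels of 5.61 in OKMS and 5.15 in Klf4S that could not be told from background. Khdc1a (1.47, from 5.09 in OKMS, and 0.74), Mmp13 (0.73 and 0.93), the stromelysin Mmp3 (0.74 and 0.61) and the deiodinase Dio3 (0.70 and 0.57) followed. Lower in both were Cnpy1 (-2.46 and -0.67), the synaptic vesicle protein Sv2b (-2.52 and -0.58), the uracil glycosylase Ung (-0.57 and -0.70), Frat1 (-0.71 and -0.53), Nat8l (-1.25 and -0.42), Pcsk1n (-2.01 and -0.41), Slc6a20a (-0.39, to 5.92 in OK+9MS, and -0.40) and Sgpp2 (-1.02 and -0.39). Within Klf4 alone, Usp50 (0.78) and Klk7 (0.72) were also among the 5 largest increases, and Ceacam2 (-0.61) and Cntd1 (-0.59, to 5.64 in Klf4L) among the 5 largest decreases.

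With the extension 14 of the 23 lists lay outside the central 95% of matched random lists in the cassette and 6 in Klf4 alone. Random lists do not keep the shared variation of a list's members, so a percentile describes these arrays and is not a test. The keratinocyte list lay above all 10000 random lists with the extension in both contexts, with a median of 1.28 in the cassette and 0.14 in Klf4 alone. In the cassette 17 of its 29 genes and 16 of 30 epithelial genes (median 1.14) were at least 2-fold higher. Also above most random lists in the cassette were the medians of the mesenchymal (0.28, percentile 99.93), smooth muscle (0.32, percentile 99.86), macrophage (0.13, percentile 99.93), endothelial (0.13, percentile 98.72) and trophoblast lists (0.12, percentile 97.55). The early pluripotency (-0.16, percentile 0.90), MYC and ribosome (-0.23, percentile 0.03) and glycolysis lists (-0.15, percentile 2.12) lay low. G2/M genes had a median of -0.50 and replication genes of -0.58 in the cassette, both below all random lists but without any G2/M gene at 2-fold. Late pluripotency genes had medians of -0.13 (percentile 0.06) in the cassette and -0.11 (percentile 0.72) in Klf4 alone. Interferon-response genes had medians of 0.19 (percentile 99.08) in the cassette and 0.12 (above all random lists) in Klf4 alone, and the 4 reprogramming factors a median of -0.22 (percentile 0.04) in Klf4 alone, where replication (-0.06, percentile 1.41) and glycolysis genes (-0.08, percentile 0.06) were low too. In the fit of both contexts limma called 0 genes, with 219 at an unadjusted p under 0.05, and with 1 residual degree of freedom that fit recovered none of the simulated changes. Across genes, which are not independent replicates, the differences in both contexts correlated at r = 0.086, a size that ranked 7 among the 28 pairs of cassettes set against the Klf4 difference.

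**Figure D2:**
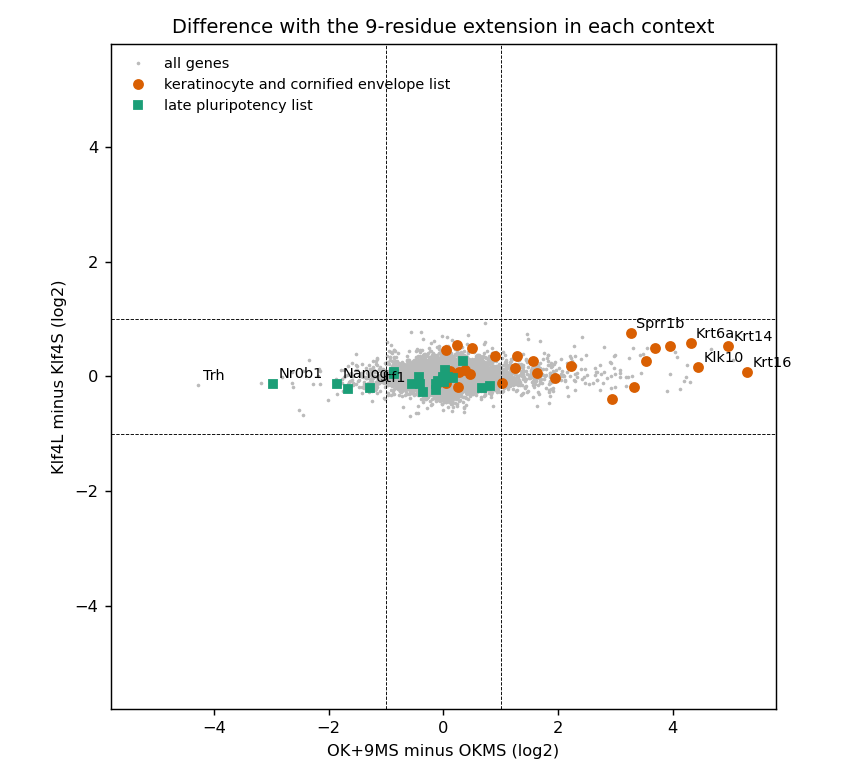
Log2 difference with the 9-residue extension in the cassette (OK+9MS minus OKMS, horizontal axis) and in Klf4 alone (Klf4L minus Klf4S, vertical axis), with 1 grey point per gene, the keratinocyte list in orange and the late pluripotency list in green; dashed lines mark 2-fold. The SD over genes was 0.418 in the cassette and 0.126 in Klf4 alone.

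The cassettes were then set against each other, each against the median of the other 7, with no replicate check. Keratinocyte genes differed most. They lay above all random lists in OSKM (median 1.57), OK+9MS (1.53), OKN-HAMS (1.70) and MKOS (0.95), and below all in STEMCCA (-1.95), WTSI (-1.50), EB-C5 (-1.42) and OKMS (-0.87). Krt14 read 12.48 in OSKM, 12.42 in OK+9MS, 12.34 in OKN-HAMS and 10.57 in MKOS, against 6.76 in STEMCCA, 6.91 in EB-C5, 6.97 in WTSI, 7.45 in OKMS and 7.01 in lacZ. The largest single differences were the keratins Krt17 in STEMCCA (-5.22) and Krt6b in EB-C5 (-5.32, to 5.96) and MKOS (-4.48), and Ly6g6c in WTSI (-5.52). In OKMS Trh (4.29) and Nr0b1 (4.09) were higher and Nccrp1 (-4.25) lower.

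Against the median of the other 7, epithelial genes had the same direction as keratinocyte genes in every cassette. They lay above all random lists in OKN-HAMS (median 1.29), OSKM (1.13), OK+9MS (1.02) and MKOS (0.59) and below all in OKMS (-0.61), STEMCCA (-1.25), EB-C5 (-1.39) and WTSI (-1.43). Against lacZ the epithelial medians of these low cassettes were 0.78 in OKMS, 0.31 in STEMCCA, 0.30 in EB-C5 and 0.21 in WTSI, so they were not below lacZ. Their keratinocyte medians against lacZ were 0.02, -0.07, -0.02 and 0.04 in the same order. The epithelial mean of OKMS (8.40) lay between those of MKOS (9.00) and STEMCCA (7.74). Against the other 7 cassettes, MKOS was low in G2/M genes (median -0.85) and replication genes (-0.85). Interferon-response genes were high in STEMCCA (0.94) and MKOS (0.65), and so were mesenchymal genes (0.61 and 0.53), which were low in OKN-HAMS (-0.50). Smooth muscle genes were low in EB-C5 (-0.76) and OKN-HAMS (-0.67). The median difference of the late pluripotency list was 0.15 in OKN-HAMS, 0.12 in OK+9MS and 0.11 in OKMS, while its mean was highest in OKMS (7.55), where 6 of its 22 genes were at least 2-fold above the median of the other cassettes, among them Nr0b1 and Utf1 (10.89). Counts of genes at 2-fold or more from the median of the other cassettes ran from 335 in MKOS to 497 in STEMCCA. Genes shared by several cassettes can count for each of them. The counts therefore do not number genes that set a single cassette apart. OSKM had 410 such genes, while 59 genes differed 2-fold between OSKM and OK+9MS and 943 between OSKM and EB-C5. Between pairs of cassettes, counts of genes at 2-fold or more ran from 59 to 1256, with a median of 648.5. The 634 genes between OKMS and OK+9MS were therefore close to the middle of the 28 pairs. Over those 634 genes, on an axis from OKMS at 0 to OK+9MS at 1, OSKM stood at 1.005, OKN-HAMS at 0.82, MKOS at 0.758, WTSI at 0.097, STEMCCA at 0.052 and EB-C5 at 0.015. On the same axis Klf4S stood at 0.595, Klf4L at 0.626 and lacZ at 0.227, so arrays without a cassette were not at 0.

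**Figure D3:**
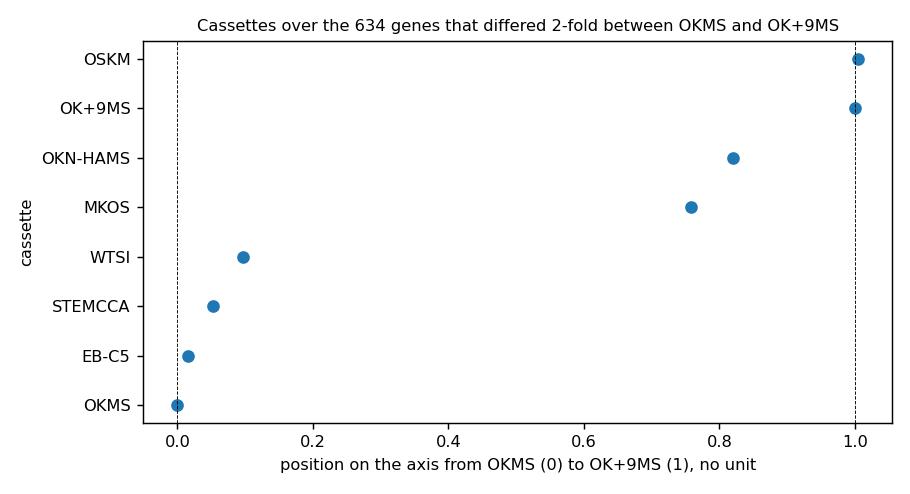
Position of each of the 8 cassettes (vertical axis) on the axis from OKMS (0) to OK+9MS (1; horizontal axis, no unit), the least-squares slope over the 634 genes that differed 2-fold between that pair, with 1 point per cassette. MKOS, OKN-HAMS and OSKM stand between 0.758 and 1.005, and EB-C5, STEMCCA and WTSI between 0.015 and 0.097.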

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

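All tests of explanations in this part were chosen after the result they bear on had been seen. Sets of 8 cassette values behind named genes, list means and counts were searched for a cassette far from the others. Not every gene named in this report was searched: Fbxo15, named further below, was left out. Of the 156 sets searched 12 were marked, where independent and unselected sets would give about 1 in 20, or 7.8. These sets were neither, since some genes were named for large differences and cell cycle genes moved together, so 7.8 sets no chance level. MKOS was low in the G2/M list mean (9.30, next lowest 9.92) and in 4 genes of the cell cycle: Plk1 (10.51), Kif23 (9.32), Asf1b (9.59) and Mcm5 (9.43). STEMCCA was low in Zdhhc23 (9.52) and Hpdl (7.74) and high in Cntd1 (6.17). WTSI was low in Apela (9.44) and high in Sox2 (7.76), EB-C5 was low in Myc (9.86), and OSKM was high in Ceacam2 (7.19).

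With the extension, Usp50 was higher in Klf4 alone (0.78) and lower in the cassette (-0.39), and Ceacam2 was lower in Klf4 alone (-0.61) and higher in the cassette (0.14); these differences between contexts were not tested. Of the 7067 probe sets with no gene or several genes, which the report did not use, limma called 246 between the cassettes and Klf4 alone, 171 higher and 75 lower, with 81 of them at 2-fold or more.

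The extension came with 634 genes at 2-fold or more in the cassette and with 0 in Klf4 alone. Noise of the OKMS or OK+9MS array is argued against, since their difference correlated at up to 0.707 in size, across genes, with differences between 2 of the other 6 cassettes. Fewer transgene-positive cells in the OKMS sort would lower the genes that rose in the cassettes against both other groups. Of these 59 genes, 30.5% were lower in OKMS than in OK+9MS. However, they were called with OKMS among the cassettes, so genes low in OKMS were less likely to be among them. The share therefore cannot decide, and this explanation is left open. Lower expression of the whole OKMS cassette goes against the direction of the Pou5f1 signal, which was 0.22 higher in OKMS than in OK+9MS and the highest of the 8 cassettes, but it is left open because no spread between repeated arrays was measured. The extension itself, another difference between single cultures, and a context in which Klf4 acts with other factors stay open as untested candidates.

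Interferon-response genes were highest in lacZ, in 15 of 23 genes. Macrophages in the unsorted lacZ culture are argued against: 0 of 20 macrophage genes lay 0.5 or more above all other arrays there, and the abundant Cd68 read 8.19 in lacZ against 8.11 to 9.62 elsewhere. Harvest on day 2, the missing sort and the lacZ transgene cannot be told apart, because the 15 genes would be highest in lacZ under any of them and a single array holds all 3. The 10 other arrays were all sorted on day 6, yet their list medians against lacZ ran from -0.18 in Klf4L and -0.20 in STEMCCA to -1.73 in OKN-HAMS. Day, sort and lacZ cannot by themselves explain these differences among the 10 arrays, whose cause was not tested.

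Cell cycle genes were lower in Klf4 alone than in the cassettes, with all 26 G2/M genes lower in both Klf4 arrays than in the other 9 arrays. The day of harvest and the sort were the same for Klf4 alone and the cassettes, so they cannot by themselves explain the difference between these groups. Against lacZ the cassettes had a G2/M median of -0.17, although MKOS alone read -0.93, with 10 of 26 genes at least 2-fold lower. That median cannot show what day and sort do in cells without the further factors, since the cassettes carry them. The absence of the other factors stays a hypothesis, and differences in the amount of Klf4 or in the density of the Klf4 cultures were not tested.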

How the results depend on the processing

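All alternatives were listed before the data were examined. Of 112 named gene results, all kept their direction in 1876 recomputed values; 323 of these values missed the threshold, and 36 results passed it under every alternative. Array numbers and single arrays limit all counts; the causes of the shifts below were not tested, except where an alternative tests fewer genes, uses fewer arrays or sets another fold.

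For the cassettes against lacZ (409 genes), the count was 199 with a minimum of 2-fold, 186 among genes above the median level, 184 on the compared groups alone and 893 with array weights, and 184 to 734 when constructs were left out in turn. For Klf4 alone against lacZ (149), it was 97 with a minimum of 2-fold, 77 among genes above the median level, 0 on the compared groups alone and 745 with array weights, and 36 to 268 with constructs left out. For the cassettes against Klf4 alone (2885), it was 811 with a minimum of 2-fold, 6492 with array weights, and 92 to 3968 with constructs left out. The lowest values came without a Klf4 construct. That leaves a lone Klf4 array and takes the small spread between the Klf4 arrays out of the shared spread. The highest came without STEMCCA or, for Klf4 alone against lacZ, without MKOS. The fit of the extension called 0 genes under all 4 of its alternatives, with 91 to 317 at an unadjusted p under 0.05.

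At 1.5-fold, counts against lacZ were 3133 for OSKM, 3725 for OKMS, 2956 for OK+9MS, 2264 for MKOS, 1778 for STEMCCA, 3667 for EB-C5, 2971 for WTSI, 3952 for OKN-HAMS, 2200 for Klf4S and 2084 for Klf4L, and 605 genes passed in all 8 cassettes. With the extension 1893 genes passed 1.5-fold in the cassette and 24 in Klf4 alone. Against the median of the other 7 cassettes, 1.5-fold counts were 1096 for OSKM, 1299 for OKMS, 936 for OK+9MS and 1385 for MKOS. They were 1730 for STEMCCA, 1698 for EB-C5, 1194 for WTSI and 1386 for OKN-HAMS. Among genes above the median level, 408 passed 2-fold with the extension in the cassette, 243 passed for OSKM against the other cassettes and 227 for OK+9MS.

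The correlation of the extension's differences was 0.0396 as Spearman's rho, a size that ranked only 18 among the 28 pairs of cassettes. Under the other alternatives it ranked from 5 (quantile normalization) to 9 (without the genes of the lists). List calls numbered 7, 7 and 12 in the order above and 0 in each comparison with an estimated correlation; fry called 1, 1 and 9. Named list results kept their direction between groups. Between single arrays, 39 list values were recomputed with the mean of the list or among genes above the median level: 0 changed sign, and 15 moved by more than the SD of the random lists.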

Other observations

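Genes of other cell types differed between the groups as well. The neural list was higher in the cassettes than in Klf4 alone, with a median of 0.23 over 19 genes (camera adjusted p = 0.02217, adjusted p = 0.263 with an estimated correlation; fry adjusted p = 0.01172), and 2 members rose over all genes and adjusted over the list alone, Nefl and Fabp7. In the same comparison the endothelial and skeletal muscle lists had medians of -0.07 and -0.02 and were lower on balance by fry (adjusted p = 0.03781 and 0.04056) and not by camera (adjusted p = 0.2882 and 0.277). The endothelial receptor Tek rose in the cassettes by 3.33 ± 0.29 SE against lacZ and by 1.65 ± 0.22 against Klf4 alone, while the endothelial adhesion molecule Esam was higher in Klf4 alone by 1.46 ± 0.21 against lacZ; the endothelial list had a median of -0.03 in the cassettes against lacZ (limma, 1 of 18 genes higher and 1 lower, Kdr by -0.52, adjusted over the list alone 2 and 3). The muscle filament gene Des was lower in the cassettes by -2.09 ± 0.26 against lacZ and by -1.45 ± 0.20 against Klf4 alone, and skeletal actin Acta1 by -1.09 ± 0.21 against Klf4 alone. The neural and glial lipid carrier Fabp7 was higher in the cassettes than in Klf4 alone by 2.77 ± 0.52, the glucose transporter Slc2a3 by 2.86 ± 0.62 and the phosphofructokinase Pfkp by 0.71 ± 0.20. The cell cycle inhibitor Cdkn2b (-1.22 ± 0.30) and the endoderm factor Gata6 (-1.24 ± 0.17) were lower in the cassettes than in Klf4 alone. The macrophage, erythroid and germline lists had medians of 0.02, -0.02 and -0.02 in the cassettes against lacZ, with 0 genes called.

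Several genes of stem cells and of blood differed widely between cassettes. They were chosen after their values were seen, have no replicate check, and for some only a few of the 8 cassette readings are given. Lin28a, an RNA-binding protein of early embryos, read 11.66 in EB-C5 and at most 8.52 elsewhere, and Fbxo15 read 7.84 in EB-C5 and at most 5.81 elsewhere. Nanog read 11.05 in OKMS, 10.60 in STEMCCA and 7.33 in WTSI, against 6.65 in lacZ. Embryonic globin Hbb-y read 9.84 in MKOS and 5.71 in STEMCCA. The haematopoietic gene Laptm5 read 10.92 in OKN-HAMS and 7.38 in WTSI, against 6.85 in lacZ.

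The relation of list means to the Pou5f1 signal over the 8 cassettes was tested after both had been seen, for 9 lists. The mesenchymal mean fell with the Pou5f1 signal (Pearson r = -0.904, exact permutation p = 0.00169, adjusted p = 0.0076, two-sided; Spearman rho = -0.905, exact permutation p = 0.00456, adjusted p = 0.0326). Without MKOS and STEMCCA, the cassettes farthest from the median Pou5f1 signal, r was -0.725 over the other 6. The MYC and ribosome mean rose with it (r = 0.921, exact permutation p = 0.00139, adjusted p = 0.0076; rho = 0.881, exact permutation p = 0.00724, adjusted p = 0.0326; r = 0.787 without the same pair). For the interferon list (r = -0.901, exact permutation p = 0.00789, adjusted p = 0.0237; rho = -0.571, exact permutation p = 0.15114, adjusted p = 0.1943) r was -0.106 without that pair, so the relation rested on MKOS and STEMCCA. The other 6 lists had adjusted exact permutation p of 0.1969 or more for Pearson's r, with 0.6184 for the epithelial and keratinocyte lists. By Spearman's rho, early pluripotency (rho = 0.833, adjusted exact permutation p = 0.0461) and DNA replication (rho = 0.81, adjusted exact permutation p = 0.049) passed 0.05, and the remaining 4 lists had 0.0825 or more. The mesenchymal list was not called lower in the cassettes than in lacZ (median -0.20, camera adjusted p = 0.4924), and its mean was higher in MKOS (11.12) and STEMCCA (11.13) than in lacZ (10.84). The purity of each sort was not measured, and no explanation of these relations was tested.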
